A study of Caenorhabditis elegans with 2 samples.

How the data were processed

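The series holds chromatin immunoprecipitation followed by sequencing (ChIP-seq) of the nuclear hormone receptor NHR-237, carried as an eGFP-tagged transgene by Caenorhabditis elegans of strain OP228. Whole L3 larvae of mixed sex were used, per the labels. The labels give 2 biological replicates of this 1 group and a fragment size range of 150 to 350 bp, and name no second condition. The comparisons are therefore between regions and between the 2 replicates, and no test between groups was made. Coverage of the control library was not used here.

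Per the file lists the submitters supplied, the authors made for each genome build, ce10 and ce11, a list of peaks and background from each replicate against a control, a list of the same kind from the pooled replicates, and a list of peaks past their irreproducible discovery rate (IDR) threshold. IDR sets how many of the ranked peaks are kept from how well ranks agree between lists; which lists set the number here, the replicates or random splits of their reads, is not given in the sources used here. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here. Each list of peaks and background holds 30000 regions in the deposited files, the ce11 IDR list 48 and the ce10 IDR list 60. Peaks were thus called per replicate and on the pooled replicates, and the IDR lists carry the pooled values. The signal of a region is the authors' own value from their peak caller. Its scale is not stated, so it was used only to rank and describe regions within a list. The signal of X and autosomal IDR peaks was compared by a permutation test on ranks, which replaced a first test on log2 signal because that test depends on the scale. The q column in the deposited lists was treated as a score, because it falls below 0 for 10776 of the 30000 pooled ce11 regions and for 4 of the 48 ce11 IDR peaks. It was not used in any test. The number of reads behind each list is not given in the sources used here, so no interval from read counts could be made; the lists all stop at the same number of regions and give no measure of depth. Exact binomial intervals (Clopper-Pearson, 95%) are given for shares of summits, and cover counting error over summits only.

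Positions are 1-based. The reference used for annotation and sequence was WBcel235, which is ce11, with Ensembl release 115 genes. The highest ends in the ce11 lists lay within the reference chromosome lengths. No ce10 position was annotated or converted. Genes of the piRNA class were left out of all annotation counts, because many lie in clusters on chromosome IV. A summit was assigned to a promoter when it lay from 1000 bp upstream to 100 bp downstream of a gene start, otherwise to exon, intron or intergenic sequence, in this order. Summits within 100 bp were counted as matched. The background for each test, unless another is named, was the set of 29952 pooled ce11 candidates that matched no IDR peak. Fisher's exact test, two-sided, was used for shares, with 0.5 added to each cell for the odds ratio only. Benjamini-Hochberg adjustment ran within each family at a threshold of 0.05. The families were 4 location classes, 7 chromosome tests, 22 gene lists, 9 gene biotypes, 10 fixed sequence motifs and 2080 6-mers within 100 bp of a summit. A biotype was counted when the summit lay inside a gene of that class or within 500 bp of either end. GC content was compared by a permutation test with 100000 permutations, two-sided. Chance overlap of the replicates' top regions came from 1000 random draws, and from 100 for the top 5000. Rank correlation over matched regions was given an interval from 1000 bootstrap draws of 1 Mb blocks. These tests take summits as units, and neighbouring summits are not independent of each other. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

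The gene lists were nuclear hormone receptors, cytochrome P450 genes, UDP-glycosyltransferases, glutathione S-transferases, lipid metabolism, cuticle collagens, heterochronic and moulting genes, ribosomal proteins, histones, chaperones, innate immunity, neuropeptides, germline, homeobox, mitochondrial respiration, vacuolar ATPase and translation factors, with marker genes of intestine, hypodermis, muscle, pharynx and neurons. The design, the lists, the motifs, the alternatives and the rule for named genes were fixed before the data were examined. Named genes were those with a start nearest to the summits of the 25 ce11 IDR peaks of highest signal (protein-coding first, then other biotypes), nhr-237, and members of the gene lists with an IDR peak at the promoter, at most 4 per list. Genes named outside this rule are marked where they appear.

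The tests were checked on simulated sets of 48 regions drawn from the pooled candidates. A set with X summits planted was called in 20 of 20 runs, 4 planted ribosomal protein promoters in 20 of 20 and a planted 6-mer in 20 of 20. The planted effects were about as large as the strongest of the IDR set, or larger, and smaller ones were not simulated. Random sets gave 0 calls in 20 runs for X, for the ribosomal list and for 6-mers, and a call of any location class in 1 of 20. Alternatives covered the genome build, matching distance, promoter length, distance to genes, window width, the background and the peak set. They also covered the top 48 regions of either replicate alone in place of the IDR set, which leaves the other replicate out of the peak set. The background there still came from the pool of both replicates, as the candidates that matched none of these 48 regions. Added after the data were seen were the IDR peaks in the top 48 of both replicates, comparisons within X and within autosomes, the chromosome test in ce10, and the chromosome test and the median signal without peaks that hold 2 sequences described in the closing observations.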

Results

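NHR-237 is a nuclear hormone receptor, a ligand-regulated class of transcription factor that is greatly expanded in nematodes. The eGFP-tagged protein was profiled by ChIP-seq in whole L3 larvae of mixed sex, in 2 biological replicates with fragments of 150 to 350 bp. Each replicate and the pool of both was represented by 30000 candidate regions in each genome build, and the authors' IDR set by 48 peaks in ce11. Read numbers were not given in the sources used here. The signal quoted for each region is the authors' own peak value, taken from the pooled replicates unless a replicate is named, and has no SD. Coordinates are ce11.

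The question of where the tagged receptor was found in the genome was addressed with the 48 IDR peaks. They were the 48 pooled regions of highest signal, with values from 42.7 to 204 and a median of 63.0. The 4 of highest signal lay on X, as did 17 of the 24 of highest signal. The peak of highest signal (204) spanned X 11094059 to 11094408, in intergenic sequence 3952 bp from the start of W02H3.3 and 1439 bp from a tRNA gene, and had a signal of 119.2 in replicate 1 and 85.9 in replicate 2. It ranked 1 in both replicates. The next (161) spanned X 9465683 to 9466032, 2513 bp from the start of ZK899.6. A signal of 137 was found at X 13700718 to 13701067, 6014 bp from the start of K02D3.1, and of 135 at X 4209101 to 4209450, 1791 bp from F20B6.9. The highest autosomal peak (131) spanned IV 11071048 to 11071187, 4091 bp from ttr-17, a transthyretin-related gene, and was 140 bp wide where the other 47 were 350 bp wide.

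Inside genes, a peak of signal 127 at X 6296435 to 6296784 lay in an intron of mom-1, named outside the rule, whose product is needed for Wnt secretion, with the nearest protein-coding start that of cest-16 at 3332 bp. A peak of 113 at X 2996986 to 2997335 lay in an intron of Y41G9A.17. A peak of 105 at X 5429401 to 5429750 lay in a coding exon of pks-1, a polyketide synthase gene also named outside the rule, 15226 bp from the start of C41A3.2. Promoter peaks on X in this group were those of nspc-17 (signal 122, X 14525752 to 14526101, summit 746 bp upstream), the snoRNA gene T27A8.8 (120, X 16056443 to 16056792, 756 bp upstream, with T27A8.7 the nearest protein-coding gene) and the insulin-like gene ins-39 (99.3, X 1344896 to 1345245, 650 bp upstream). Neighbouring peaks at X 8036252 to 8036601 (87.1) and X 8036460 to 8036809 (54.97) lay upstream of the non-coding gene C18A11.13. The nearest protein-coding gene to both was xol-1, a switch gene of sex determination and dosage compensation, with its start 4886 and 4678 bp away. The X peaks nearest to fbxb-58, F55G7.5, gtr-1, T24D8.6, ZC53.1 and F56C3.1 had signals of 114.5, 111, 93.5, 64.4, 63.8 and 63.3 and were intergenic. The autosomal peaks among the 25 included those at the promoters of cdc-48.1, an AAA ATPase gene (103.6, II 10563385 to 10563734, 153 bp upstream), the ribosomal protein gene rpl-3 (89.04, III 3867384 to 3867733, 295 bp upstream), egg-5 (70.1, I 4171995 to 4172344, 581 bp upstream), eelo-2 (63.5, IV 17249730 to 17250079, 226 bp upstream) and the constitutive chaperone gene hsp-1 (62.7, IV 17278394 to 17278743, 390 bp upstream). A peak of 64.8 at V 1151323 to 1151672 lay in an exon of the non-coding gene linc-128, 4773 bp from the calmodulin gene cmd-1. A peak of 63.7 at II 5543380 to 5543729 lay 1309 bp from ins-13 and 43 bp upstream of the spliced leader RNA gene sls-2.2.

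**Figure D1:**
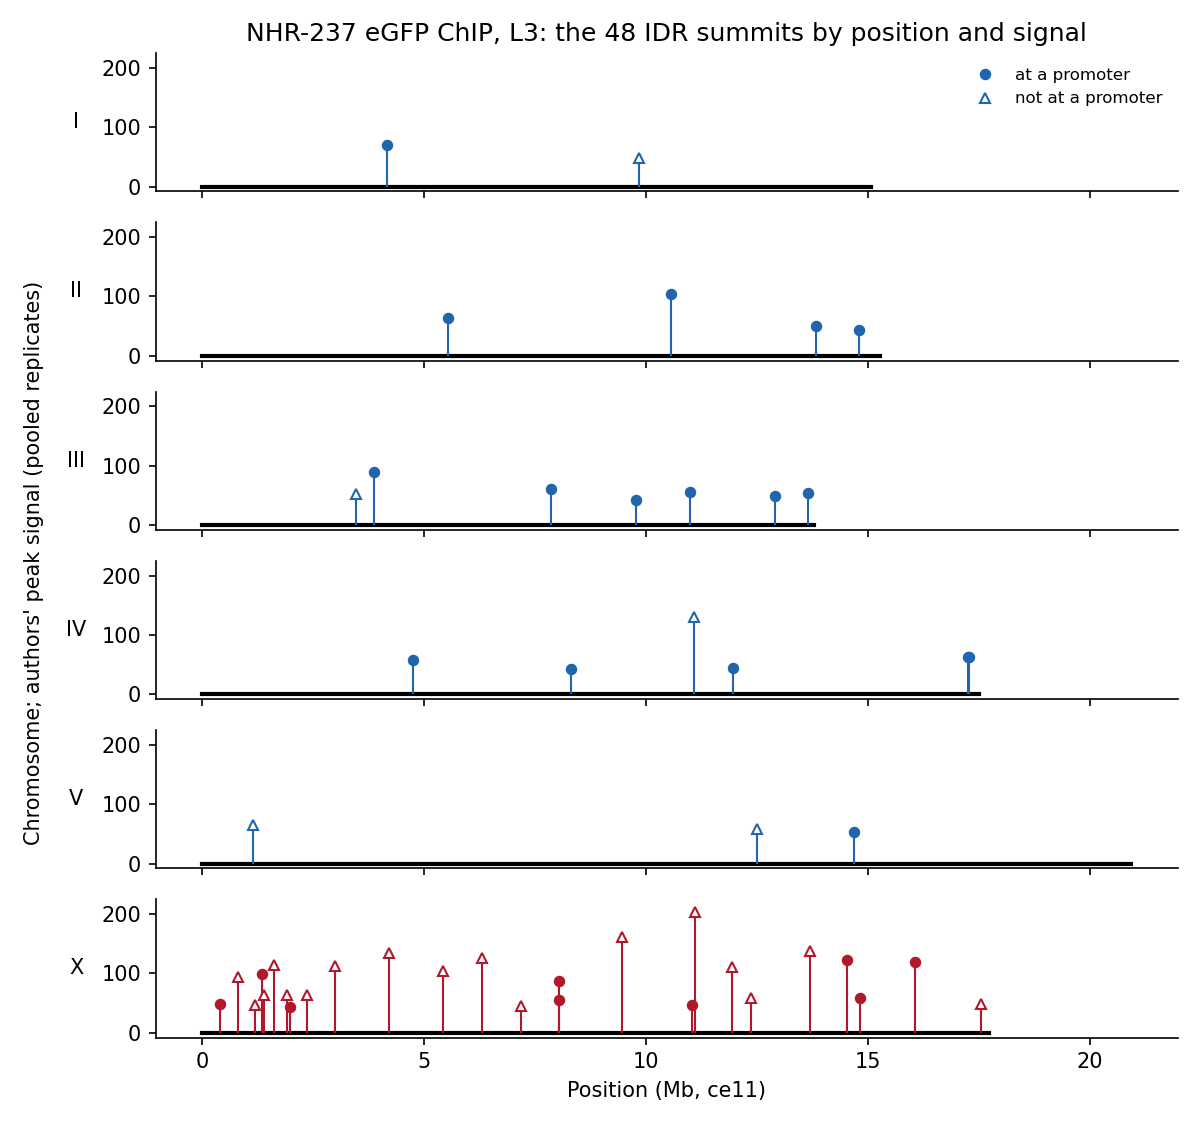
Position of the 48 IDR summits along each ce11 chromosome (horizontal axis, Mb) with the authors' peak signal from the pooled replicates (vertical axis, no unit stated); filled circles lie at promoters and open triangles do not, X is red and autosomes are blue. X carries 26 of the summits, including that of highest signal (204).

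The distribution over chromosomes was compared with that of the 29952 other pooled candidates. X held 26 of the 48 IDR summits, or 54.2% (95% interval 39.2 to 68.6%), against 20.4% of the candidates (odds ratio 4.59, Fisher's exact test, adjusted exact p = 1.9e-06). V held 3 of 48, or 6.25%, against 21.03% (Fisher's exact test, adjusted exact p = 0.040). Each autosome was set against all other summits, X included, so the excess on X lowers the share of every autosome. The V call is therefore not separate from that on X. The shares on I (2 summits), II (4), III (7) and IV (6) did not pass the test, with adjusted exact p from 0.13 to 0.67. Chromosome arms held 72.9% of IDR summits and 60.8% of candidates (adjusted exact p = 0.18). Signal had a median of 90.3 at the X peaks and 56.5 at the autosomal peaks (permutation test on ranks, two-sided, p = 0.015, chosen after the values were seen). The X share was 45.8% among the top 48 regions of replicate 2 alone and 52.1% among those of replicate 1 alone. When 14 X peaks that hold either of 2 sequences picked after the data were seen were left out, X held 12 of 34 peaks, or 35.3%, and the test was no longer passed (adjusted exact p = 0.32). Those 12 X peaks had a median signal of 56.9. Both values follow in part from the choice, which took out X peaks alone, 13 of them among the 17 of highest signal, by sequences found at these same peaks. The V call was lost with the 24 IDR peaks of highest signal (adjusted exact p = 0.15), the top 48 regions of replicate 1 alone (0.18), the IDR peaks in the top 48 of both replicates (0.38), without those 14 peaks (0.32) and in ce10 (0.056).

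The annotation at the summits showed that 26 of 48 IDR summits (54.2%, 95% interval 39.2 to 68.6%) lay at a promoter, against 29.7% of candidates (odds ratio 2.78, Fisher's exact test, adjusted exact p = 0.00085). Promoters of non-coding genes were counted, and 17 of these 26 summits lay at the promoter of a protein-coding gene. Intergenic summits were also more frequent, at 33.3% against 15.9% (Fisher's exact test, adjusted exact p = 0.0025). Exons held 8.33% against 28.7% (adjusted exact p = 0.0015) and introns 4.17% against 25.6% (adjusted exact p = 0.00072). The X and autosomal peaks differed in this. A promoter held 17 of 22 autosomal summits (77.3%), such as those of rpl-3, cdc-48.1 and hsp-1. On X it held 9 of 26 (34.6%), such as those of nspc-17, ins-39 and the non-coding genes T27A8.8 and C18A11.13. The shares differed (Fisher's exact test, p = 0.0042, chosen after the values were seen). Against candidates of their own chromosomes, the autosomal share passed the test (29.4% of autosomal candidates, adjusted exact p = 1.9e-05) and the X share did not (31.3% of X candidates, adjusted exact p = 0.68), whereas intergenic sequence held 53.8% of X summits and 19.7% of X candidates (adjusted exact p = 0.00047). The promoter call was lost with the 24 IDR peaks of highest signal (37.5% at promoters, adjusted exact p = 0.38). It was lost too with the IDR peaks in the top 48 of both replicates (40%, adjusted exact p = 0.28). The top 48 regions of replicate 2, which leave replicate 1 out of the peak set, also lost it (41.7%, adjusted exact p = 0.15). In that last setting the exon, intron and intergenic calls were lost too (adjusted exact p = 0.15 each), and the intron call also with the 24 highest peaks (0.080), in the top 48 of both (0.054) and within X (0.085), the exon call within autosomes (0.14), and the intergenic call within autosomes (0.76), where its direction reversed.

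**Figure D2:**
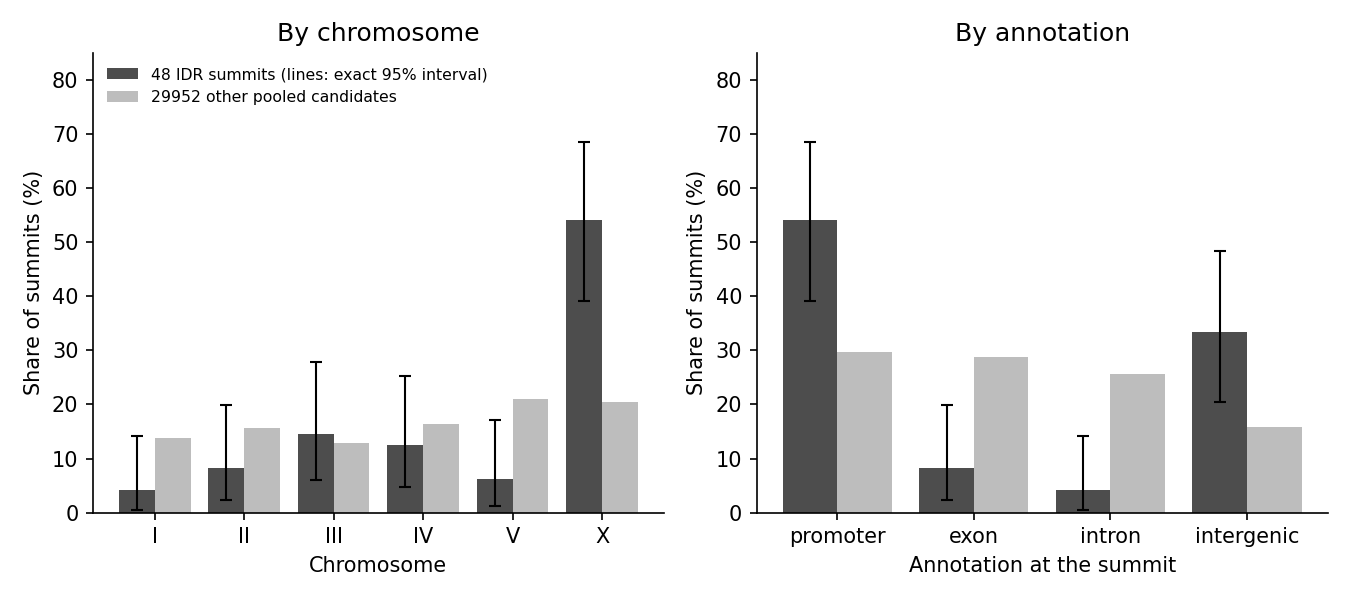
Share of summits (%) by chromosome and by annotation for the 48 IDR summits (dark bars, with exact 95% intervals) and the 29952 other pooled candidates (light bars). X holds 54.2% of IDR summits against 20.4% of candidates, and promoters 54.2% against 29.7%.

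The genes at these promoters were 36, of which 19 were protein-coding and 17 belonged to other classes. Ribosomal protein genes were the only list of 22 past the threshold, with rpl-3, rpl-35 and rpl-20 among the 36 genes against 30 of 9894 genes with a candidate at the promoter (Fisher's exact test, adjusted exact p = 0.0049). The peak of rpl-35 had a signal of 60.1 (III 7854529 to 7854878, 430 bp upstream), and that of rpl-20 a signal of 57.1 (IV 4749901 to 4750250, 298 bp upstream). The latter summit also lay 164 bp upstream of Y17G9B.5, on the opposite strand, a gene named outside the rule. Chaperones had hsp-1 (adjusted exact p = 0.51), mitochondrial respiration had the cytochrome c oxidase gene cox-5A (49.8, III 12905003 to 12905352, 313 bp upstream, adjusted exact p = 0.51), and neuropeptides had ins-39 (adjusted exact p = 1). No nuclear hormone receptor gene was among the 36 (95% upper bound 9.74%), against 84 of 9894 in the background (adjusted exact p = 1). Likewise 0 of the 36 genes belonged to the lists of cytochrome P450 genes, UDP-glycosyltransferases, glutathione S-transferases, lipid metabolism, cuticle collagens, heterochronic and moulting genes, histones, innate immunity, germline, homeobox, vacuolar ATPase and translation factors, or to the markers of intestine, hypodermis, muscle, pharynx and neurons. These 0 counts had adjusted exact p = 1 each. Background shares of the lists with 0 genes, nuclear hormone receptors included, ran from 0.0505 to 1.04%. With 36 genes a count of 0 is then likely for each list, and the tests could not show depletion. The ribosomal call was lost with the 2000 next candidates as background (adjusted exact p = 0.051) and with the 24 peaks of highest signal, which hold rpl-3 alone (adjusted exact p = 0.80). With promoters of 2000 bp, mitochondrial respiration also passed (2 genes, adjusted exact p = 0.020).

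Small non-coding genes lay near several peaks. An snRNA gene was within 500 bp of 3 of 48 IDR summits (6.25%) and 0.124% of candidates (Fisher's exact test, adjusted exact p = 0.00033). The genes were sls-2.4 (36 bp from the summit, peak signal 70.1, in the same peak as egg-5), sls-2.2 (43 bp, 63.7) and R07E5.16 (67 bp, 55.9, III 10989437 to 10989786, named outside the rule). Both sls genes encode spliced leader RNA, which is joined to the start of many nematode mRNAs. A tRNA gene was near 3 summits, all on X (6.25% against 0.728%, adjusted exact p = 0.012). A gene of the ncRNA class was near 10, among them C18A11.13 (20.8% against 7.83%, adjusted exact p = 0.011). Fewer IDR summits than candidates lay inside or within 500 bp of a protein-coding gene, at 56.3% against 77.3% (adjusted exact p = 0.0065). This count covers whole genes and not their starts alone. The lincRNA, miRNA, snoRNA, antisense RNA and pseudogene classes did not pass (adjusted exact p from 0.28 to 1). None of these classes passed with the top 48 regions of replicate 2 alone, where snRNA genes were near 1 of 48 summits (adjusted exact p = 0.19). The tRNA call was also lost with replicate 1 alone (adjusted exact p = 0.11), the 24 highest peaks (0.29), the top 48 of both (0.30), within autosomes (1) and within 1000 bp (0.092), the ncRNA call with the 2000 next candidates (0.059), the 24 highest peaks (0.65), the top 48 of both (0.66), within X (1) and within 1000 bp (0.11), the snRNA call with the top 48 of both (0.14), and the protein-coding call within autosomes (0.79) and within 1000 bp (0.098).

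The sequence within 100 bp of the summits was compared with fixed motifs and with all 6-mers. AGGTCA, the core sequence bound by many nuclear receptors, was at 3 of 48 IDR summits (6.25%) and 5.01% of candidates (Fisher's exact test, adjusted exact p = 0.82). The variant AGTTCA was at 10.4% and 14.3% (adjusted exact p = 0.82). GAGAGA was at 13 of 48 (27.1%) against 11.5% (adjusted exact p = 0.024), but none of the other settings fixed beforehand kept this call (adjusted exact p from 0.11 to 0.78). Autosomal summits against autosomal candidates, a comparison added after the data were seen, kept it (8 of 22, 36.4% against 11.8%, adjusted exact p = 0.026). The other motifs, CACGTG, CANNTG, TGATAA, GGGCGG, TTTTTTTT, TGACGTCA and TTCNNGAA, did not pass, with adjusted exact p from 0.34 to 1. Of 2080 6-mers, 42 passed, all of them more frequent at IDR summits. The lowest p belonged to CCCTGC, at 16 of 48 summits (33.3%) against 2.27% of candidates (adjusted exact p = 1.4e-11). CCTGCG, GCGCGA and CTGCGC were each at 29.2% against 2.13, 2.31 and 2.35%, and CGCGCA at 31.3% against 2.90%. CCCTGC was at 15 X summits and 1 autosomal summit, and CCCTTC at 14 and 1. AGCGCG was at 1 X summit and 8 autosomal summits, and ACACAC at 7 and 8. X summits against X candidates gave 33 6-mers, 24 of them among the 42. Autosomal summits against autosomal candidates gave 8, led by AGCGCG (36.4% against 1.95%, adjusted exact p = 1.2e-05), 6 of them among the 42. GC content was 41.98% ± 7.12 (SD, 48 summits) against 36.6% ± 6.44 in the candidates (permutation test, two-sided, p = 1e-05, the smallest that the permutations can give). The difference of 5.40 percentage points fell to 1.11 with 250 bp on each side of the summit (permutation p = 0.12). With a GC-matched background 21 6-mers passed, 20 of them among the 42.

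**Figure D3:**
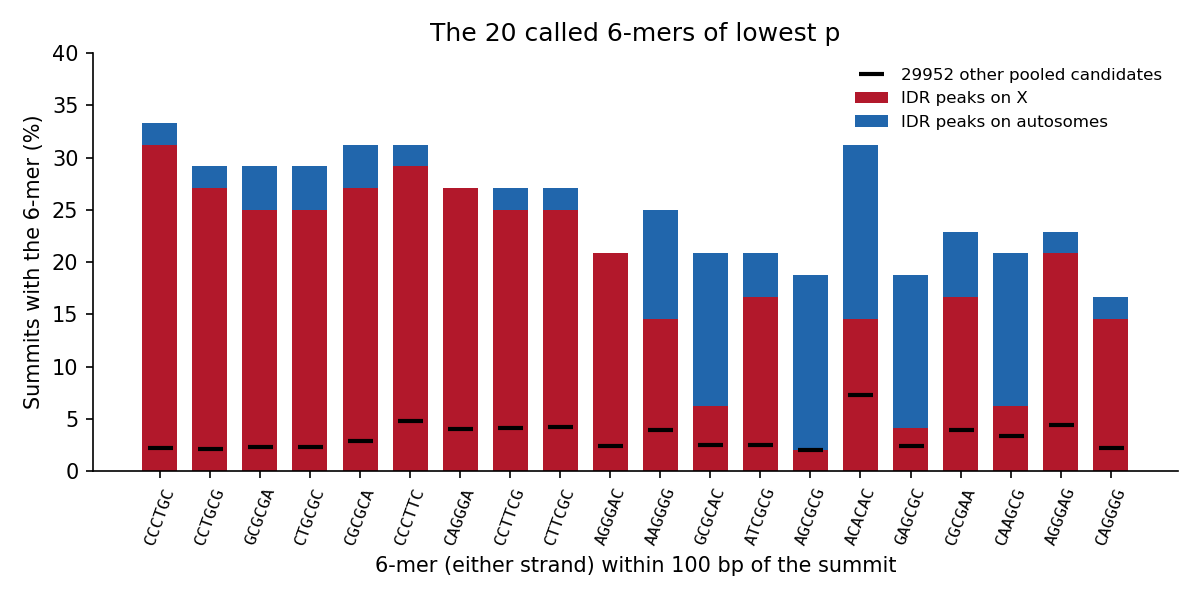
Share of the 48 IDR summits (%) with each of the 20 called 6-mers of lowest p within 100 bp, split into X (red) and autosomal (blue) peaks; black marks give the share of the 29952 other pooled candidates. CCCTGC was at 15 X peaks and 1 autosomal peak, AGCGCG at 1 and 8.

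The replicates were compared through their own candidate lists. Among the top 48 regions by signal, 25 of replicate 1 were matched in replicate 2 (52.1%, 95% interval 37.2 to 66.7%), against a chance mean of 0.0229% (Fisher's exact test over the 6118 regions matched in both lists, one-sided, p = 6.5e-51). Further down the lists the share was lower, at 9.40% of the top 500 (chance 0.339%), 6.80% of the top 1000 (chance 0.684%) and 7.26% of the top 5000 (chance 3.40%). Over the matched regions Spearman's rho of signal was 0.086 (95% block interval 0.061 to 0.109). This correlation is across regions, which are not independent replicates. Of the 48 IDR peaks, 40 (83.3%) were in the top 48 of replicate 1 and 29 (60.4%) in the top 48 of replicate 2. All 48 were in the top 500 of replicate 1, and 38 in that of replicate 2. The 10 others, 7 of them on X, included the second peak upstream of C18A11.13 (rank 28 in replicate 1, 3732 in replicate 2), the peak at R07E5.16 (17 and 3404) and the peak 1056 bp from T24D8.6 (16 and 910). Some ranked far lower in replicate 2, at 13299 (X 17544428 to 17544777), 21396 (IV 8311911 to 8312260) and 26929 (IV 11961752 to 11962101). The last had a signal of 7.81 there, where the lowest in the list was 7.41. The peak at X 7181639 to 7181988 had no replicate 2 candidate within 100 bp. The peaks at rpl-3 (19 and 14), cdc-48.1 (13 and 13), hsp-1 (20 and 43) and ins-39 (4 and 17) were in the top 48 of both. Whether the replicates differ in depth could not be read from lists of equal length.

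**Figure D4:**
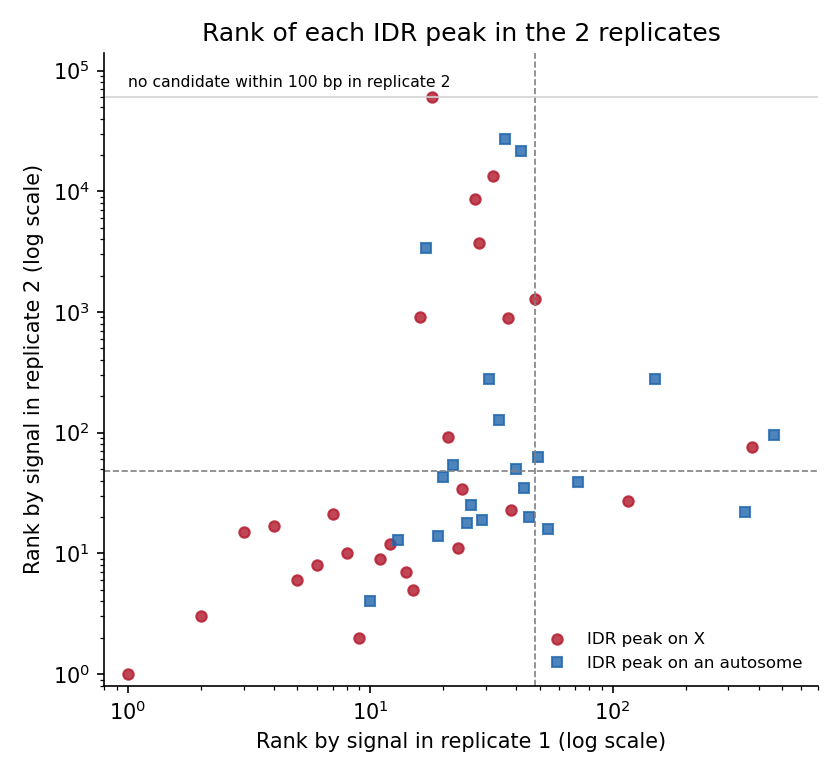
Rank by signal of each IDR peak in replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), X in red circles and autosomes in blue squares; dashed lines mark rank 48. The peaks of highest rank in replicate 1 rank high in replicate 2, and 10 peaks rank beyond 500 or are unmatched in replicate 2.

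The nhr-237 gene itself (WBGene00021610, V 1625189 to 1626820, minus strand) had no IDR peak and no candidate summit within 10 kb in replicate 1, replicate 2 or the pool. With 20 kb on each side, the window held 3 candidates in replicate 1, 2 in replicate 2 and 4 in the pool, against a median of 13 in windows of the same size in each list. The highest signal in the pooled window was 22, at percentile 12.95 of such windows. The percentile was 66.9 in replicate 1 and 3.71 in replicate 2, so the height of the highest candidate did not place the window alike in the replicates. The nearest summit to the gene start was 13503 bp away in replicate 1, 16865 bp in replicate 2 and 13633 bp in the pool. The stretch without a candidate summit was 31735, 37412 and 33609 bp long, respectively, against a median spacing of 2221 bp in the pool. Its part common to the 3 lists, V 1608588 to 1640323, holds 10 protein-coding genes. These include the nuclear hormone receptor genes nhr-177, nhr-179, nhr-117, nhr-110 and nhr-238 next to nhr-237, which were named after the stretch was seen.

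**Figure D5:**
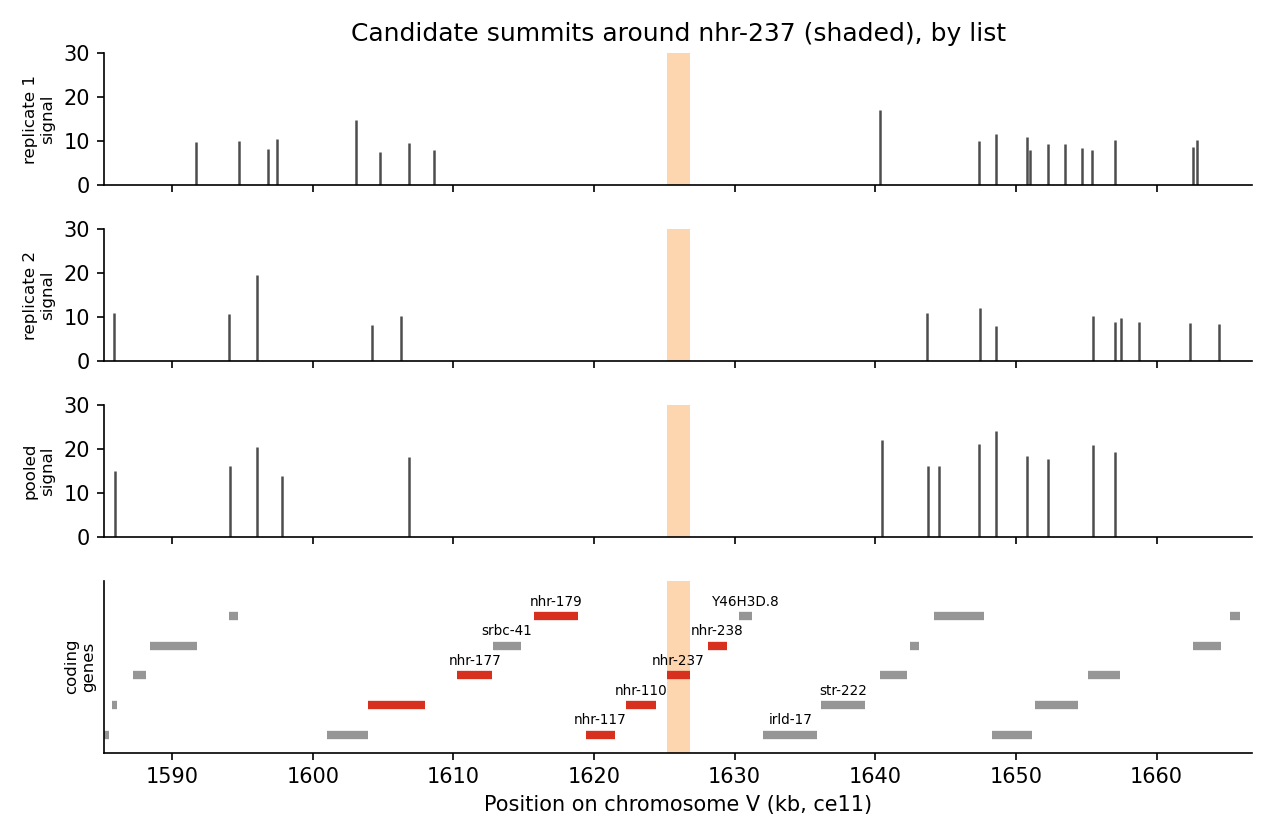
Candidate summits within 40 kb of nhr-237 on V (horizontal axis, kb, ce11) with the authors' signal (vertical axis, no unit stated) in replicate 1, replicate 2 and the pool, above the protein-coding genes (nuclear hormone receptor genes in red). No summit falls between 1608588 and 1640323 in any of the 3 lists.

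The authors' sets for the 2 genome builds were set side by side by count. The ce10 set held 60 peaks and the ce11 set 48, and each was made of the pooled regions of highest signal in its build. X carried 29 of 60 ce10 peaks (48.3%) and 26 of 48 ce11 peaks (54.2%), and chromosome II 8 and 4. Among the 48 ce10 peaks of highest signal, X held 56.3%. Positions were not compared between builds.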

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

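The IDR peaks in the top 48 of both replicates, the comparisons within X and within autosomes, the ce10 chromosome test and the test without peaks holding either sequence were chosen after the data were seen; the other alternatives were planned. Of 191 alternative values over 26 results, 110 stayed the same, 48 lost a call, 31 moved, 1 gained a call and 1 reversed. Those that stayed kept their direction and side of the threshold, lay within their spread or, for counts, within a fixed fold of the main count. By this fold, 60 ce10 peaks against 48, and 62 6-mers with replicate 1 alone against 42, stand as the same. The cause was not tested unless stated. The X odds ratio stayed past the threshold in the alternatives fixed beforehand, 3.30 to 9.08, and in ce10, and fell to 2.16 (adjusted exact p = 0.32) without the peaks holding either sequence, which removes X peaks by construction. The promoter odds ratio was 1.45 with the 24 peaks of highest signal, 1.70 to 2.36 with a replicate left out, 1.60 in the top 48 of both and 1.19 within X (Fisher's exact test). The intergenic odds ratio reversed to 0.696 within autosomes (adjusted exact p = 0.76). Only 21 of the 24 peaks of highest signal were in the top 48 of both replicates. The replicate overlap was 9.40% for the top 500, 6.80% for 1000 and 7.26% for 5000; IDR peaks were found at 100% in the top 500 and the top 1000 of replicate 1 and at 79.2% and 83.3% in those of replicate 2. Promoter genes numbered 13 in the top 48 of both and 19 when only protein-coding. Gene lists past the threshold, 1 in the main comparison, were 0 with the 2000 next candidates, 0 with the 24 highest peaks, 0 within X and 2 with promoters of 2000 bp. Gene biotypes past it, 4 in the main comparison, were 2 with the 24 highest peaks, 0 to 3 with a replicate left out, 1 in the top 48 of both, 2 within X, 2 within autosomes and 1 within 1000 bp. Fixed motifs past it, 1 in the main comparison, were 0 with the 2000 next candidates, the 24 highest peaks, either replicate left out, the top 48 of both, X alone, 50 bp, 250 bp and a GC-matched background, and 1 within autosomes (GAGAGA, adjusted exact p = 0.026). The 42 6-mers became 21 with a GC-matched background and 8 within autosomes, a smaller set. The GC difference was 1.11 points with 250 bp (permutation p = 0.12). Arms against centres gained a call with the 2000 next candidates (odds ratio 2.16, adjusted exact p = 0.029). The number of reads, which was not given, limits what can be said of the weaker regions of replicate 2.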

Other observations

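The tests on the X share, on motif sites, on the proteins at the X sites, on chance spacing and on extra copies of the tagged locus, the second sequence, its count, the rank groups and the mismatch limits were chosen after the results they concern were seen. The thresholds of the GC and uniqueness tests were set before those values were seen. The motif-site test was changed 3 times after its values were seen. Unmerged copies at the top 48 regions and merged sites with any candidate also had higher shares on X. With at most 1 mismatch, a candidate was at 12 of 27 merged sites on X and 5 of 37 on autosomes (Fisher's exact test, p = 0.0092). Of these, 9 on X and 0 on autosomes had a top 48 summit, so the higher share on X rests on the peaks that the motif was picked from. A form that left out sites with an IDR summit was dropped because it removed sites on X alone. The spacing test replaces a count of spacings, with its limit of 1% kept.

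Some of the X peaks carried a sequence that was found at no autosomal peak. All 7 of the 6-mers inside TCGCGCAGGGAG, a 12-bp motif known from recruitment sites of the X chromosome dosage compensation complex and recalled here without a source at hand, were among the 42 called 6-mers. With at most 2 mismatches, the motif was within 100 bp of 13 of 26 X IDR summits (50%, 95% interval 29.9 to 70.1%) and 0 of 22 autosomal ones. The motif was looked for because its 6-mers were called at these same summits, mostly on X, so these counts describe the peaks and do not test the difference. An exact copy lay at the peak in the intron of Y41G9A.17 (X 2996986 to 2997335), and copies with 1 mismatch at the peaks near W02H3.3, F20B6.9, nspc-17, T27A8.8 and gtr-1, in the intron of mom-1, in the exon of pks-1 (both named outside the rule) and at the stronger peak upstream of C18A11.13 and xol-1. The motif was at 0.359% of the other X candidates and 0.302% of the autosomal candidates. Another sequence seen among the called 6-mers, TCCCTTCGC, was at 9 X and 0 autosomal IDR summits and at 17 of 29952 candidates. The share of X among pooled regions fell with rank, from 11 of the top 12 and 15 of the next 36 to 30.8% of the next 52, 25.5% of the next 400 and 20% of the 20000 of lowest signal.

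For the 26 of 48 IDR summits on X, a background raised along the whole chromosome was tested first. The 2000 next candidates held X at 22.65%, below the lower bound of 39.2% for the IDR set. A rise along X could lift its share mostly among the highest signals, and the X share fell step by step with rank. The test therefore cannot decide on a raised background, which stays open. Signal at starts of active genes was tested next. X summits lay at promoters less often than autosomal summits (Fisher's exact test, p = 0.0042, the comparison already given for these peaks), which argues against it as the whole cause and leaves it open for the 9 X summits at promoters. A biological difference between samples could not be tested, because the design has 1 group.

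For the motif at X summits, GC composition was tested with X candidates matched on GC, of which 0.385% held it, below the lower bound of 29.9%. That bound is for a motif picked from these same summits. With adjustment over all 2080 6-mers, CCCTGC, which lies inside the motif, kept its call at the 48 IDR summits against a GC-matched background (odds ratio 13.4, Fisher's exact test, adjusted exact p = 8.7e-07). The motif sequence alone was tested with its genomic sites, copies within 200 bp merged; with at most 1 mismatch, a top 48 summit was within 100 bp of 9 of 27 sites on X (95% interval 16.5 to 53.96%) and 0 of 37 on autosomes (upper bound 9.49%), and with at most 2, of 13 of 269 (2.60 to 8.12%) and 0 of 1340 (upper bound 0.275%). The motif was picked because its 6-mers were called at these same summits, mostly on X. These counts therefore cannot decide whether X and autosomal sites differ. Multiplied by the 2080 6-mers searched, Fisher's exact p is 1.3e-07 with at most 2 mismatches and 0.35 with at most 1. This factor does not correct for the choice of the motif. The 13 X sites include the 9 of at most 1 mismatch, and such copies were denser on X (1.81 against 0.448 per Mb). With at most 1 mismatch, most sites on X and all on autosomes had no top 48 summit, so such a copy was not by itself enough for one. What stays open is which protein was at the 14 X summits that hold either sequence. NHR-237 may bind there, or dosage compensation sites may be recovered irrespective of the tagged protein, and a ChIP of an untagged strain or another tagged factor, not used here, is needed to separate these.

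For the stretch without candidates over nhr-237, sequence that cannot be mapped uniquely was tested with 32-mers of the stretch, of which 93.9% occurred once in the genome. Chance spacing was tested with the other 19972 protein-coding genes. Of these, 165 (0.826%, 95% block interval 0.298 to 1.54%) have their start in a pooled stretch as long. The interval includes the limit of 1%, and most of these stretches had under 80% unique 32-mers, unlike that over nhr-237. The share therefore cannot decide on chance spacing, which stays open. By count, the first measure used, 18 of the other 29993 spacings (0.0600%) were as long. Of the 19 pooled spacings at least as long, that over nhr-237 included, 3 had at least 80% unique 32-mers, and that over nhr-237 had the highest share. Another candidate explanation that stays open is that extra copies of the tagged locus in the transgenic strain raised the control there, over the 31735 bp shared by the 3 lists. The coverage of the control, not used here, would decide it.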
